A study of Saccharomyces cerevisiae CEN.PK113-7D with 6 samples.

How the data were processed

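Transcript levels were measured with single-channel GeneChip arrays for yeast, hybridised with biotin-labelled total RNA of Saccharomyces cerevisiae CEN.PK113-7D from 3 batch samples and 3 chemostat samples. The deposited values are log2 signals, 1 per probe set and array, which the authors made with PLIER, per the submitters' processing notes. Its version, background correction, offset and between-array step are not given in the sources used here. That the values are on a log scale, and that its base is 2, was inferred from their range (4.95 to 13.3 over the 6 arrays); if the base differed, each log2 change would be multiplied by a constant. Values were used as deposited, with no further scaling. A pseudocount planned for linear values was not applied, because the values were already logarithms. The number of arrays limits the precision.

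Of 10928 probe sets, 5498 belonged to 1 S. cerevisiae gene each, 213 were controls and 1 named several genes. S. pombe was assigned to the 1746 whose gene lay outside the S. cerevisiae table and had a lower-case symbol. The other 3470 fell in none of these classes and are called unannotated. S. pombe probe sets without a lower-case symbol would be among them. Symbols were updated through a reference gene table of assembly R64, which also gave the chromosome and position of each gene and was used for nothing else. Of the 47 genes with several probe sets, the brightest on average stood for the gene; for 1 of them the probe sets passed in opposite directions. The 5449 genes were tested together. For 116 of them the probe set carries a suffix for shared or cross-hybridising probes, HXT7 and many ribosomal protein genes included. HXT6, HXT16 and TDH2 were not analysed here, nor were the listed names ARG5,6, DUR1,2, ADE5,7 and MEL1.

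Chemostat was compared with batch, without covariates, by limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Errors of changes are limma's standard errors, and those of group means are SDs over 3 arrays. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 32 lists with at least 3 measured members. Isozyme pairs were tested with limma on the difference between both genes on each array, adjusted over the pairs. Chromosomes and the genes within 30 kb of a chromosome end were tested with camera. The files used here give no detection calls, so the 95th percentile of the S. pombe probe sets (5.94) stood for background. A gene below it in 1 group only has a bound, the bright group's mean over the dim group's mean of, per array, the higher of that array's S. pombe percentile and the gene's own signal.

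Gene lists, pairs, tests, the choice of named genes and most other settings were set before the data were examined. The text names the 10 largest rises and falls among genes that passed and whose groups did not overlap; for each list, the 3 passing members with the largest change and the largest in the other direction; 20 measured diagnostic genes; the pairs that moved in opposite directions; and the 3 S. pombe probe sets that changed most. Names outside that rule (pairs that did not pass or that lost or gained a call, pairs that are not isozymes, members that do not do what their list's name says, genes at background in a figure, gene families in the closing section) were chosen after their values were seen. Some listed names are aliases: YRS1 led to YOR1, and MRP8 and RPP1 entered by a name pattern.

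The other settings set then were quantile normalization, centring on the gene median or on the S. pombe median, a filter on dim genes, a trended and robust variance, array weights, the mean of a gene's probe sets, each replicate left out, all probe sets tested, an adjusted p under 0.01, limma's treat at 1.5-fold, camera with an estimated correlation, fry, and pairs without shared probe sets. Background subtraction and a comparison of 2 arrays per group were added after the data were seen. The array weights were estimated by an iteration that stopped with a convergence warning.

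The scripts were tested on simulated data of 5449 genes with the arrays' own spread, for the comparison of chemostat with batch. Of 50 genes shifted by each size, 56% were recovered at 0.25 log2 units, 96% at 0.5, and 100% at 1 and at 2, with 8 false calls among 184. The list shifted by 0.5 log2 units was called, and 0 of the lists that share no member with it were. All 10 pairs with 1 gene shifted by 1 log2 unit were called, as were 2 pairs without a shifted gene. Smaller differences within pairs were not simulated. Noise was drawn independently for each gene, whereas the correlation estimated from the arrays was 0.67 in the stress list. The simulation therefore cannot show how often camera's preset correlation calls lists of correlated genes wrongly. RNA sequencing of the same extractions was not analysed here.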

Results

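The data describe the transcripts of the haploid laboratory yeast Saccharomyces cerevisiae CEN.PK113-7D, of mating type a, grown on glucose in batch culture or in a chemostat. A batch culture receives no fresh medium, whereas a chemostat is fed and drained continuously so that the cells grow at a constant rate. Total RNA from 3 batch samples (replicates 1, 2 and 3) and 3 chemostat samples (replicates 4, 8 and 9) was labelled with biotin and hybridised to 6 GeneChip arrays. The series was made to compare arrays with RNA sequencing of the same RNA extractions. The sequencing was not analysed here, and the comparison left to the arrays is that of the cultivation modes. The labels state that biomass was sampled at steady state; dilution rate, limiting nutrient and growth phase of the batch samples are not given in the sources used here. Nothing says that replicates were separate cultures, so p-values measure the spread between these samples, which may be technical. Values are signals per gene on a log scale whose base is taken as 2 from its range, and a floor near 5 compresses changes of dim genes. Changes are chemostat minus batch, and n = 3 arrays per group throughout.

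The arrays separated completely by cultivation mode. The first principal component held 97.3% of the variance over 5449 genes and parted the batch arrays from the chemostat arrays. Pearson correlations across genes lay between 0.994 and 0.997 within batch, between 0.995 and 0.999 within chemostat and between 0.815 and 0.853 across groups; genes are not independent replicates. No array repeated another. The median gene signal lay between 7.95 and 7.97 on all 6 arrays. Signals of probe sets for the fission yeast Schizosaccharomyces pombe, which serve here as background, had a 95th percentile of 5.94. For 10 control transcripts with probe sets at both ends, the 3' end exceeded the 5' end by 0.249 ± 0.052 (log2, SD) in batch and by 0.171 ± 0.011 in chemostat (two-sided exact permutation p = 0.1, the smallest that 3 against 3 arrays allow). The difference between groups rested on 18S rRNA, whose 5' end was brighter (-2.91 in batch, -3.92 in chemostat). Over the 9 other transcripts the 3' excess was 0.601 ± 0.021 in batch and 0.626 ± 0.053 in chemostat (two-sided exact permutation p = 0.4). That mean joins opposite shifts. For ACT1, SPT15, URA3 and WBP1 the 3' minus 5' difference was larger on every chemostat array than on any batch array. For TDH1 and RIP1 it was smaller, and for EAF5, SRB4 and 25S rRNA the groups overlapped. The TDH1 transcript itself rose by 2.43 log2 units in chemostat. The p-value over the 9 transcripts therefore does not show that the 3' excess was equal in both groups. Replicate 1 stood apart among the batch arrays, with 59 genes more than 0.5 log2 units above the mean of replicates 2 and 3 and 9 below it. Chemostat replicate 4 was above replicates 8 and 9 by that margin for 25 genes and below for 32.

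Most genes differed between the modes. In limma's moderated test with Benjamini-Hochberg adjustment, 1829 genes were higher and 2442 lower in chemostat, and 1178 did not pass. Large changes were mostly rises: 204 genes rose and 16 fell by 4-fold or more. The median size of a called rise was 0.47 log2 units and that of a called fall was -0.46. At least a 1.5-fold change was required in a stricter test (limma's treat), which left 601 higher and 564 lower. The groups did not overlap for 4451 of all 5449 genes (81.7%), against the 10% of genes that chance gives. Of the calls, 125 concerned genes below background in both groups.

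The 10 largest rises comprised SIP18 and GRE1, which encode hydrophilins induced by desiccation and osmotic stress; RGI2, a respiratory growth gene; JEN1, the lactate and pyruvate permease; ADY2, an acetate transporter; ADH2, the alcohol dehydrogenase that oxidises ethanol; SFC1, the mitochondrial succinate-fumarate carrier; FDH1, a formate dehydrogenase; SPG4; and YDL218W. SIP18 was at background in batch (5.57 ± 0.07, SD) and at 12.44 ± 0.17 in chemostat, at least 88.9-fold higher (adjusted p = 4.71e-10). The bound was at least 101.8-fold for GRE1, 61.4-fold for RGI2, 64.2-fold for JEN1, 38.6-fold for ADY2, 26.2-fold for SFC1, 28.9-fold for YDL218W and 32.2-fold for FDH1, each bound setting the chemostat mean against the higher of background and the gene's own signal on each batch array. ADH2 and SPG4 were above background in both groups and rose by 5.56 (SE 0.074) and 5.36 (SE 0.071) log2 units. YDL218W varied most within chemostat (SD 0.88), where replicate 4 differed from the mean of the others by -1.52.

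The largest falls were led by glucose transporters. HXT3 fell by 3.81 log2 units (SE 0.13, adjusted p = 8.10e-08), from 11.48 ± 0.02 to 7.67 ± 0.31. HXT1 dropped to background in chemostat and was at least 7.56-fold lower there, and HXT4 fell by 2.72 (SE 0.13). UTR2, a cell wall chitin transglycosylase, fell by 2.83 (SE 0.080). FET3, the multicopper oxidase of high-affinity iron uptake, fell by 2.76 (SE 0.40), with chemostat replicate 4 lying 1.63 above the mean of replicates 8 and 9. FSH1, a serine hydrolase, fell by 2.39, ARI1, an NADPH-dependent aldehyde reductase, fell by 2.25, and EEB1, an ethyl ester synthase, fell by 2.22. YDL241W was at least 4.37-fold lower and ended at background. STE2, the receptor for alpha pheromone, fell by 2.13 (SE 0.16).

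The 33 gene lists fixed before the data were examined were tested with camera at a preset inter-gene correlation of 0.01, which compares a list with all other genes. Of 32 lists with at least 3 measured members, 14 passed as higher and 7 as lower. None passed when the correlation was estimated from these arrays, where 4 lists had an unadjusted p under 0.05. That setting rests on the few residual degrees of freedom of 6 arrays, which limits its power. Its correlations also lay above the preset in all lists but the hypoxic genes (0.0055) and alpha-cell markers (0.0007). Estimates were 0.67 for stress, 0.55 for trehalose and glycogen, 0.47 for the respiratory chain and 0.43 for ribosome biogenesis. The preset p-values of such lists may therefore be too small. Ribosome biogenesis, with 102 of 102 genes lower, had a camera adjusted p of 0.292 there, but genes that move together can give such a count. A call that ended with the estimated correlation is shown to be neither wrong nor right. Fry, which asks whether a list moves one way without comparing it with other genes, passed 26. The 9 other ways of parting the 6 arrays into 3 and 3 passed between 18 and 24 lists with the preset correlation. Each of them holds unequal numbers of batch and chemostat arrays in its groups, so part of the mode difference remains. These splits therefore cannot show how many lists would pass without a difference between modes. Counts of members stand beside each list's test below. Some lists share members, so their results are not independent. The stress list holds HXK1 and GLK1 of glycolysis, PGM2 of trehalose and glycogen, and GND2 of the pentose phosphate list. It also holds CYC7, which is in the respiratory and hypoxic lists, and CIT3 is in both the gluconeogenesis and the tricarboxylic acid cycle lists. Counts adjusted over the list alone equalled those over all genes in 31 lists; the 2 others are named where they occur. Medians use fitted changes. With genes at background in 1 group held at their bounds, they would be 2.65 for gluconeogenesis, 2.85 for stress, 0.22 for nitrogen catabolite repression, 0.25 for sugar use and 0.18 for meiosis.

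**Figure D1:**
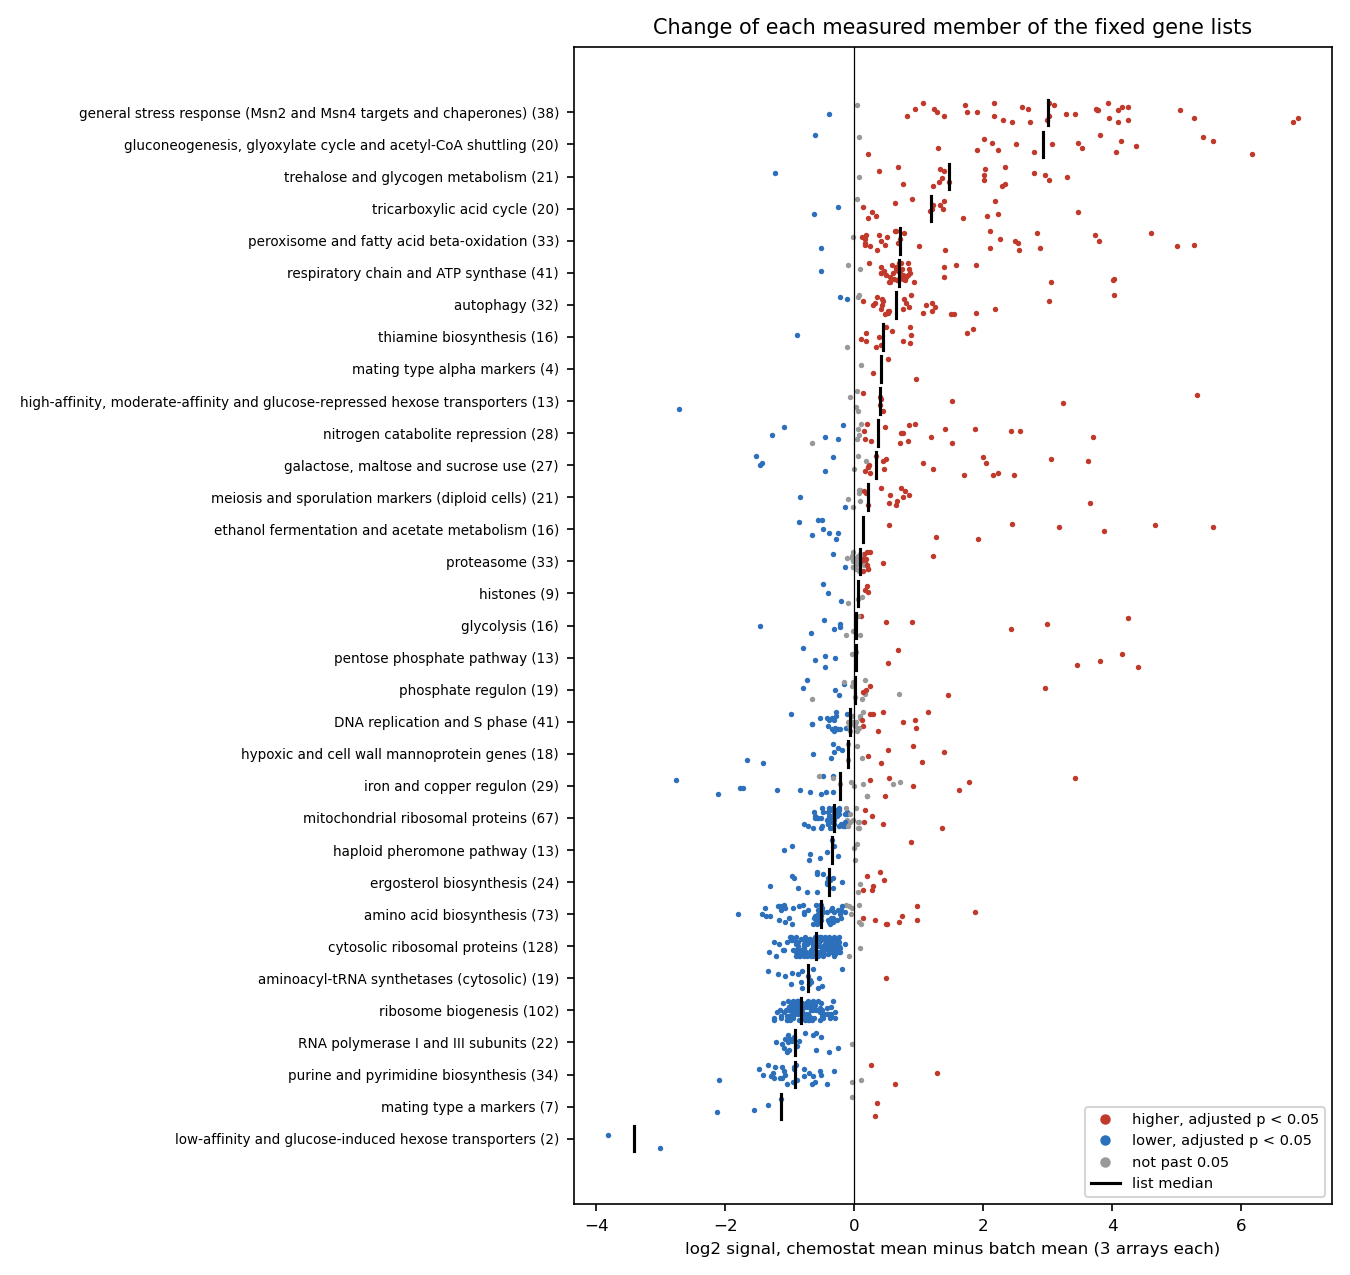
Each point is a measured member of a fixed gene list, placed by its log2 signal in chemostat minus batch (means of 3 arrays each), red or blue where limma's adjusted p was under 0.05 and grey where it was not; black bars are list medians and the number of measured members is in brackets. Genes at background in 1 group are drawn at their fitted change. The stress list has a median of 3.001, while all 102 ribosome biogenesis genes lie below 0.

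Hexose transporters moved in both directions. HXT1 and HXT3, the low-affinity transporters of high glucose, both fell. Among 13 measured members of the high-affinity, moderate-affinity and glucose-repressed set, 8 rose, 1 fell and 4 did not pass. HXT5 rose from background to 10.99 ± 0.18, at least 31.9-fold, and HXT7, a high-affinity transporter, rose by 3.24 (SE 0.22). HXT4 was the member that fell; 2 members fell without batch replicate 3 and 3 after quantile normalization. The set was higher by camera (median 0.40, adjusted p = 0.019), but not with an estimated correlation (adjusted p = 0.292 with an estimated correlation). That call also ended after quantile normalization (median 0.13, adjusted p = 0.109) and after removal of genes below background (median 1.51, adjusted p = 0.252), which left 3 higher members, since 8 members were below background in both groups. HXT7 in batch stood at 9.18 in replicate 1 and lay 0.91 higher there than in the others; its probe set carries the suffix of shared probe sets, and HXT6 was not analysed here.

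Glycolysis split. Of 16 measured genes, 6 rose, 6 fell and 4 did not pass, and the list did not differ from other genes (median 0.02, camera adjusted p = 0.653). HXK1 rose by 4.25 (SE 0.24), GLK1 by 2.98 (SE 0.19) and TDH1, a glyceraldehyde-3-phosphate dehydrogenase, by 2.43 (SE 0.28). HXK2, the main hexokinase of glucose-grown cells, fell by 1.46 (SE 0.045). These 3 rising genes were also higher in batch replicate 1 than in the other batch arrays, by 1.01 for HXK1, 0.81 for GLK1 and 1.11 for TDH1. In the list of ethanol fermentation and acetate metabolism, 8 genes rose and 8 fell (camera adjusted p = 0.307). Those that rose most were ADH2, ACS1, the acetyl-CoA synthetase used during aerobic growth on acetate (4.66, SE 0.043), and ALD4, the mitochondrial aldehyde dehydrogenase (3.88, SE 0.22). ADH4 fell by 0.86 (SE 0.051), and ADH1, the enzyme that makes ethanol, fell by 0.50 (SE 0.039). The pentose phosphate list also divided, with 6 of 13 genes higher, 5 lower and 2 not passing (camera adjusted p = 0.292). TKL2 rose by 4.40 (SE 0.14), GND2 by 4.15 (SE 0.11) and NQM1 by 3.81 (SE 0.31), whereas RKI1 fell by 0.80 (SE 0.084). Batch replicate 1 differed from the mean of the other batch arrays by 1.27 for NQM1 and by 0.79 for ALD4. The gap was 0.22 for TKL2, 0.04 for GND2 and -0.19 for RKI1.

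Gluconeogenesis, the glyoxylate cycle and acetyl-CoA shuttling rose nearly throughout. Of 20 genes, 18 rose, 1 fell and 1 did not pass, with a median of 2.92 (camera adjusted p = 1.04e-08; adjusted p = 0.292 with an estimated correlation). JEN1, ADY2 and SFC1 led the list. ICL1, the isocitrate lyase of the glyoxylate cycle, rose by 4.06 (SE 0.17). Malate synthase MLS1 was at least 11.1-fold higher and FBP1, the fructose-1,6-bisphosphatase, at least 4.88-fold, both from background in batch. PCK1, phosphoenolpyruvate carboxykinase, rose by 1.90 (SE 0.31), and its signal in chemostat replicate 4 lay 1.30 above the mean of replicates 8 and 9. That gap was 0.87 for FBP1, 0.77 for MLS1, 0.65 for ICL1 and -0.23 for JEN1. Its median over the list was 0.21. CIT2, the peroxisomal citrate synthase, fell by 0.61 (SE 0.12).

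Mitochondrial respiration genes were higher as well. In the tricarboxylic acid cycle list 17 of 20 genes rose, 2 fell and 1 did not pass (median 1.19, camera adjusted p = 3.12e-06; adjusted p = 0.292 with an estimated correlation). CIT3 rose by 3.47 (SE 0.090), from a batch mean of 5.98 that lay barely above background (5.94). The succinate dehydrogenase subunits SDH1 and SDH2 rose by 2.24 and 2.18 (SE 0.062 for each), while IDH2 fell by 0.62 (SE 0.052). Of 41 genes of the respiratory chain and ATP synthase, 38 rose, 1 fell and 2 did not pass (median 0.70, camera adjusted p = 8.15e-11; adjusted p = 0.292 with an estimated correlation). GUT2, the mitochondrial glycerol-3-phosphate dehydrogenase, rose by 4.02 (SE 0.076), the external NADH dehydrogenase NDE2 was at least 13.7-fold higher, CYB2 rose by 3.06 (SE 0.14), and DLD1 fell by 0.51 (SE 0.065); 2 genes fell after quantile normalization. CYC1, cytochrome c, did not pass (11.38 in batch, 11.47 in chemostat, adjusted p = 0.230); without batch replicate 1 it passed at 0.16 (adjusted p = 0.020), and after quantile normalization at 0.26 (adjusted p = 0.002459).

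Peroxisomal and reserve carbohydrate genes followed. Peroxisome and fatty acid beta-oxidation genes rose in 31 of 33 cases, with 1 lower and 1 not passing (median 0.71, camera adjusted p = 9.00e-11; adjusted p = 0.240 with an estimated correlation). CTA1, the peroxisomal catalase, POT1, the 3-ketoacyl-CoA thiolase, and POX1, the acyl-CoA oxidase, were at least 25.2-fold, 19.7-fold and 15.4-fold higher, and PEX25 fell by 0.51 (SE 0.040). Trehalose and glycogen genes numbered 19 higher, 1 lower and 1 not passing (median 1.47, camera adjusted p = 5.95e-08; adjusted p = 0.292 with an estimated correlation). Glycogen phosphorylase GPH1 rose by 3.31 (SE 0.12), from a batch mean of 5.97 that lay barely above background (5.94). Phosphoglucomutase PGM2 rose by 3.02 (SE 0.14) and the branching enzyme GLC3 by 2.97 (SE 0.12), and the minor phosphoglucomutase PGM1 fell by 1.23 (SE 0.069).

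The general stress response gave a median of 3.001. It had 36 of 38 genes higher, 1 lower and 1 not passing (camera adjusted p = 3.12e-14; adjusted p = 0.292 with an estimated correlation). Besides SIP18 and GRE1, DDR2 rose by 5.28 (SE 0.17), and the small heat shock proteins HSP26 and HSP12 rose by 5.06 (SE 0.077) and 3.94 (SE 0.34). MSN4, which encodes a transcription factor of this response, fell by 0.40 (SE 0.084). The list's median lay 0.24 higher in batch replicate 1 than in replicates 2 and 3, and for HSP12 that gap was 1.44. Autophagy genes showed 28 of 32 higher, 2 lower and 2 not passing (median 0.65, camera adjusted p = 1.10e-08; adjusted p = 0.292 with an estimated correlation). ATG39, a receptor for autophagy of the nuclear envelope, was at least 15.55-fold higher, its batch mean lying below the percentile of the batch arrays themselves. ATG34 rose by 3.02 (SE 0.083) and the peroxisome receptor ATG36 by 2.19 (SE 0.051), while ATG27 fell by 0.22 (SE 0.052); 1 gene instead of 2 was lower without batch replicate 3, chemostat replicate 8 or chemostat replicate 9, and with arrays centred on the S. pombe median.

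Genes for protein synthesis were lower. Of 128 members of the list of cytosolic ribosomal proteins, 126 fell and 2 did not pass (median -0.59, camera adjusted p = 3.67e-16; adjusted p = 0.292 with an estimated correlation). RPL13A fell by 1.33 (SE 0.039), RPL41A fell by 1.25 (SE 0.22) and RPS26B fell by 1.22 (SE 0.045); many of these genes have near-identical copies that a probe set cannot separate. RPP1, which fell by 0.75 (SE 0.056), entered the list by its name and encodes a subunit of ribonucleases P and MRP. With quantile normalization, S. pombe centring, array weights or 2 arrays per group, 1 member was higher. All 102 ribosome biogenesis genes fell (median -0.82, camera adjusted p = 3.67e-16; adjusted p = 0.292 with an estimated correlation), and among them NOP1 fell by 1.25 (SE 0.048), HAS1 fell by 1.23 (SE 0.056) and NOP13 fell by 1.20 (SE 0.049). RNA polymerase I and III subunits fell in 21 of 22 cases (median -0.92, camera adjusted p = 2.39e-06; adjusted p = 0.292 with an estimated correlation). RPA49 fell by 1.22 (SE 0.053), RPB8 fell by 1.12 (SE 0.067) and RPA34 fell by 1.09 (SE 0.045).

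Cytosolic aminoacyl-tRNA synthetases were lower for 18 of 19 list members (median -0.72, camera adjusted p = 1.04e-04; adjusted p = 0.308 with an estimated correlation). WRS1 fell by 1.33 (SE 0.056), MES1 fell by 1.17 (SE 0.066) and FRS1 fell by 1.08 (SE 0.049). The member that rose was YOR1 (0.49, SE 0.079), a plasma membrane transporter of the ABC family that entered through an alias in the fixed list and is no synthetase. Of 67 members of the mitochondrial ribosomal protein list, 51 fell, 5 rose (8 with S. pombe centring) and 11 did not pass (median -0.31, camera adjusted p = 3.99e-04; adjusted p = 0.540 with an estimated correlation). MRPL3 and RSM26 fell by 0.77 (SE 0.042) and 0.72 (SE 0.046). MRP8, which rose by 1.37 (SE 0.053), entered by its name and is not an established part of the mitochondrial ribosome.

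Most genes for amino acid and nucleotide synthesis were lower. Among amino acid genes 57 of 73 fell, 9 rose and 7 did not pass (median -0.51, camera adjusted p = 3.62e-05; adjusted p = 0.371 with an estimated correlation). SER2 fell by 1.80 (SE 0.064) and LEU9 fell by 1.43 (SE 0.054), whereas BAT2, the cytosolic branched-chain aminotransferase, rose by 1.87 (SE 0.060). In purine and pyrimidine synthesis 29 of 34 genes fell, 3 rose and 2 did not pass (median -0.92, camera adjusted p = 1.10e-05; adjusted p = 0.361 with an estimated correlation). IMD4, an IMP dehydrogenase, fell by 2.10 (SE 0.048), ADE8 fell by 1.48 (SE 0.085) and ADE4 fell by 1.41 (SE 0.043), and URA10 rose by 1.29 (SE 0.052). Genes under nitrogen catabolite repression rose in 18 of 28 cases, with 5 lower and 5 not passing (median 0.37, camera adjusted p = 0.00135; adjusted p = 0.292 with an estimated correlation). The proline permease PUT4 rose by 3.70 (SE 0.062), the NAD-dependent glutamate dehydrogenase GDH2 by 2.57 (SE 0.049) and CAR2 by 2.43 (SE 0.10), and OPT2 ended at background, at least 1.65-fold lower.

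Most genes for sugar use and thiamine rose. Of 27 genes for galactose, maltose and sucrose use, 19 rose, 5 fell and 3 did not pass (median 0.34, camera adjusted p = 5.24e-04; adjusted p = 0.292 with an estimated correlation). MAL32, a maltase, rose by 3.63 (SE 0.086), the maltose permease MAL11 by 3.05 (SE 0.055), and SUC2, invertase, by 2.05 (SE 0.048). SIP4, a transcriptional activator of gluconeogenic genes, was at least 3.89-fold higher. STD1, which acts in glucose sensing, fell by 1.52 (SE 0.048), the repressor gene MIG1 rose by 0.34 (SE 0.057), and GAL1, galactokinase, was at least 1.16-fold higher, from background in batch. Thiamine genes rose in 14 of 16 cases, with 1 lower and 1 not passing (median 0.45, camera adjusted p = 0.00103; adjusted p = 0.292 with an estimated correlation). THI13 rose by 1.84 (SE 0.048), THI4 by 1.74 (SE 0.16) and SNZ1 by 0.89 (SE 0.084), and THI80, thiamine pyrophosphokinase, fell by 0.88 (SE 0.054), with 2 lower after quantile normalization. The probe sets of MAL32 and THI13 carry the suffix of shared probe sets, so their rises may include signal of related genes.

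Ergosterol, hypoxic, iron, copper and phosphate genes did not differ from other genes as lists in camera's test. Of 24 ergosterol genes 16 fell, 6 rose and 2 did not pass (median -0.38, camera adjusted p = 0.101), and the list passed as lower with fry (adjusted p = 0.000264); ERG4 fell by 1.31 (SE 0.049), ERG26 fell by 0.97 (SE 0.057) and NCP1 fell by 0.94 (SE 0.040), and ERG6 rose by 0.46 (SE 0.048). Hypoxic and cell wall mannoprotein genes divided into 6 higher, 8 lower and 4 not passing, with a median of -0.09 and a mean of -0.04 although camera placed them on the higher side (adjusted p = 0.830), a side that turned after quantile normalization (median -0.28, adjusted p = 0.840). TIR3 fell by 1.67 (SE 0.079), CYC7, the hypoxic cytochrome c, rose by 1.40 (SE 0.079), and AAC3 was at least 2.61-fold lower, at background in chemostat. Iron and copper genes were split into 7 higher, 12 lower and 10 not passing (median -0.22, camera adjusted p = 0.791). The median was -0.024 without batch replicate 2, where camera's direction turned (adjusted p = 0.912), -0.34 with array weights and -0.37 with 2 arrays per group. The copper transporter CTR3 rose by 3.42 (SE 0.48), FET3 was among the largest falls, and ENB1, a siderophore transporter, fell by 2.11 (SE 0.20). The CTR3 signal of batch replicate 1 differed from the mean of the other batch arrays by -1.48. Chemostat replicate 4 differed from the mean of replicates 8 and 9 by -1.08 for CTR3, 1.63 for FET3 and 0.58 for ENB1. Among 19 phosphate genes 5 rose, 5 fell and 9 did not pass (median 0.01, camera adjusted p = 0.653); PHM7 rose by 2.96 (SE 0.28), PHM8 was at least 1.85-fold higher and VTC1 fell by 0.79 (SE 0.050). PHM7 lay 1.11 higher in batch replicate 1, and without that array 8 phosphate genes were higher. There were 9 with array weights or 2 arrays per group, and 3 after quantile normalization.

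Proteasome and cell cycle genes had medians near 0. Of 33 proteasome genes 15 rose, or 14 adjusted over the list alone, 2 fell and 16 did not pass (median 0.10, camera adjusted p = 0.027; adjusted p = 0.501 with an estimated correlation). The call also ended without batch replicate 1 (adjusted p = 0.056). RPN4, the transcription factor of proteasome genes, rose by 1.22 (SE 0.087), RPN5 rose by 0.45 (SE 0.042) and RPN13 fell by 0.32 (SE 0.065). DNA replication genes were 10 higher, 18 lower and 13 not passing of 41 (median -0.07, camera adjusted p = 0.791). RNR2 and RNR4, subunits of ribonucleotide reductase, rose by 1.15 (SE 0.063) and 0.96 (SE 0.064), and the cyclin CLB6 fell by 0.97 (SE 0.057). Of 9 histone genes 3 rose, 3 fell and 3 did not pass, and the median (0.06) and mean (-0.05) differed in sign (camera adjusted p = 0.776). HHT2 fell by 0.49 (SE 0.064) and HTB2 fell by 0.41 (SE 0.075), whereas HTA1 rose by 0.22 (SE 0.036).

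Several transcripts of a cells were lower in chemostat. Of 7 a-cell markers 4 fell, 2 rose and 1 did not pass (median -1.14, camera adjusted p = 0.481). STE2 fell by 2.13, the protease BAR1 fell by 1.56 (SE 0.11) and the pheromone gene MFA2 fell by 1.33 (SE 0.16), while ASG7 rose by 0.35 (SE 0.044). The median of these markers lay 0.42 higher in chemostat replicate 4 than in replicates 8 and 9. Of 4 alpha-cell markers 3 rose, or 4 adjusted over the list alone (median 0.41, camera adjusted p = 0.041; adjusted p = 0.292 with an estimated correlation), and the call ended without chemostat replicate 4 (adjusted p = 0.051) and after quantile normalization (median 0.25, adjusted p = 0.166). MF(ALPHA)1, the alpha pheromone gene, was at background in batch and at least 1.502-fold higher in chemostat, STE3 rose by 0.53 (SE 0.069) and SAG1 by 0.29 (SE 0.039). In the haploid pheromone pathway 9 of 13 genes fell, 1 rose and 3 did not pass (median -0.35, camera adjusted p = 0.110), a list that passed as lower without chemostat replicate 4 (adjusted p = 0.041). SST2 fell by 1.09 (SE 0.069) and FAR1 fell by 0.97 (SE 0.073), and RME1, a repressor of meiosis, rose by 0.87 (SE 0.13). Among 21 meiosis and sporulation markers 13 rose, 2 fell and 6 did not pass (median 0.21, camera adjusted p = 0.00327; adjusted p = 0.292 with an estimated correlation), and 9 were below background in both groups. Quantile normalization ended that call (median 0.034, adjusted p = 0.166), with 5 lower, and 7 were higher and 1 lower after removal of dim genes (median 0.66). SPS100 was at least 11.1-fold higher, IME1 rose by 0.85 (SE 0.081) and SPS4 was at least 1.69-fold lower.

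**Figure D2:**
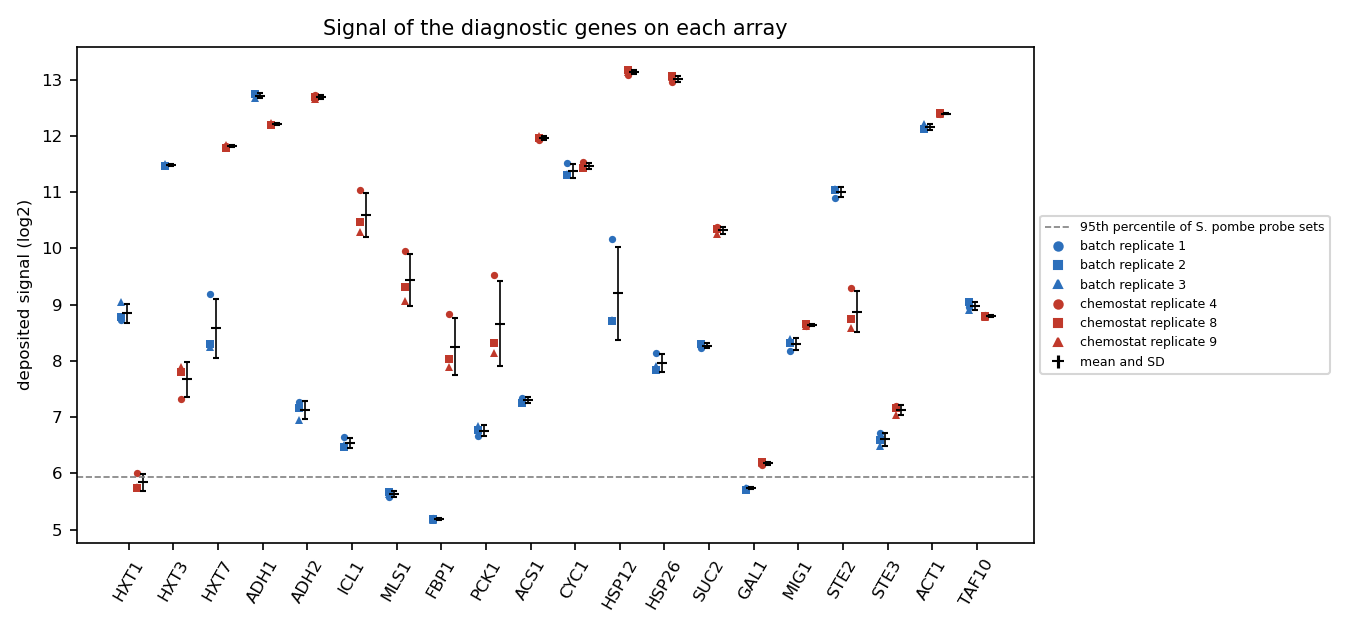
Deposited log2 signal of 20 diagnostic genes on each of the 6 arrays (batch blue, chemostat red, one symbol per replicate), with the mean and SD of each group beside the points and the 95th percentile of S. pombe probe sets dashed. ADH2 rises from 7.13 to 12.69 between groups, whereas CYC1 stays at 11.38 and 11.47, and batch replicate 1 lies above the other batch arrays for HSP12 and HXT7.

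Genes often used as references moved slightly. ACT1, actin, rose by 0.23 (SE 0.041, adjusted p = 8.97e-04), and TAF10 fell by 0.18 (SE 0.048, adjusted p = 0.00825).

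Paired genes of related function often changed apart. Most pairs are isozymes; HXT7 and HXT1 are transporters, MIG2 and MIG1 repressors, HEM13 and HEM14 successive heme enzymes, and GAD1 and GDH1 a decarboxylase and a dehydrogenase. In 39 of 43 measured pairs the difference between the changes of both genes passed limma's test, and in 19 pairs one gene rose while the other fell. HXT7 rose by 3.24 while HXT1 fell to background, at least 7.56-fold. ADH2 against ADH1 differed by 6.07 (SE 0.082), HXK1 against HXK2 by 5.70 (SE 0.29) and ACS1 against ACS2 by 5.05 (SE 0.079). The remaining pairs with a rising first gene and a falling second gene were IDP2 and IDP1, TKL2 and TKL1, GND2 and GND1, PGM2 and PGM1, SOL4 and SOL3, SSA4 and SSA2, PDC6 and PDC1, BAT2 and BAT1, URA8 and URA7, and ENO1 and ENO2. The order was opposite for LEU9 and LEU4, CIT2 and CIT1, AAC3 and PET9, MIG2 and MIG1, and HEM13 and HEM14. No difference passed for NTH2 and NTH1 (adjusted p = 0.101), GLG1 and GLG2 (adjusted p = 0.136), HMG1 and HMG2 (adjusted p = 0.428), or ADH5 and ADH1 (adjusted p = 0.833). Without batch replicate 1, NTH2 and NTH1 (-0.21, adjusted p = 0.026) and GLG1 and GLG2 (0.19, adjusted p = 0.041) passed, as did GLG1 and GLG2 with background subtracted (0.26, adjusted p = 0.036), NTH2 and NTH1 after quantile normalization (-0.22, adjusted p = 0.040), and both pairs with array weights (adjusted p = 0.028 and 0.033) or 2 arrays per group (adjusted p = 0.00441 and 0.021). The LYS21 and LYS20 difference (0.29, adjusted p = 0.043) lost its call without each array but batch replicate 1, with values from 0.22 to 0.32 in those 5 fits, and after quantile normalization (0.17, adjusted p = 0.229).

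**Figure D3:**
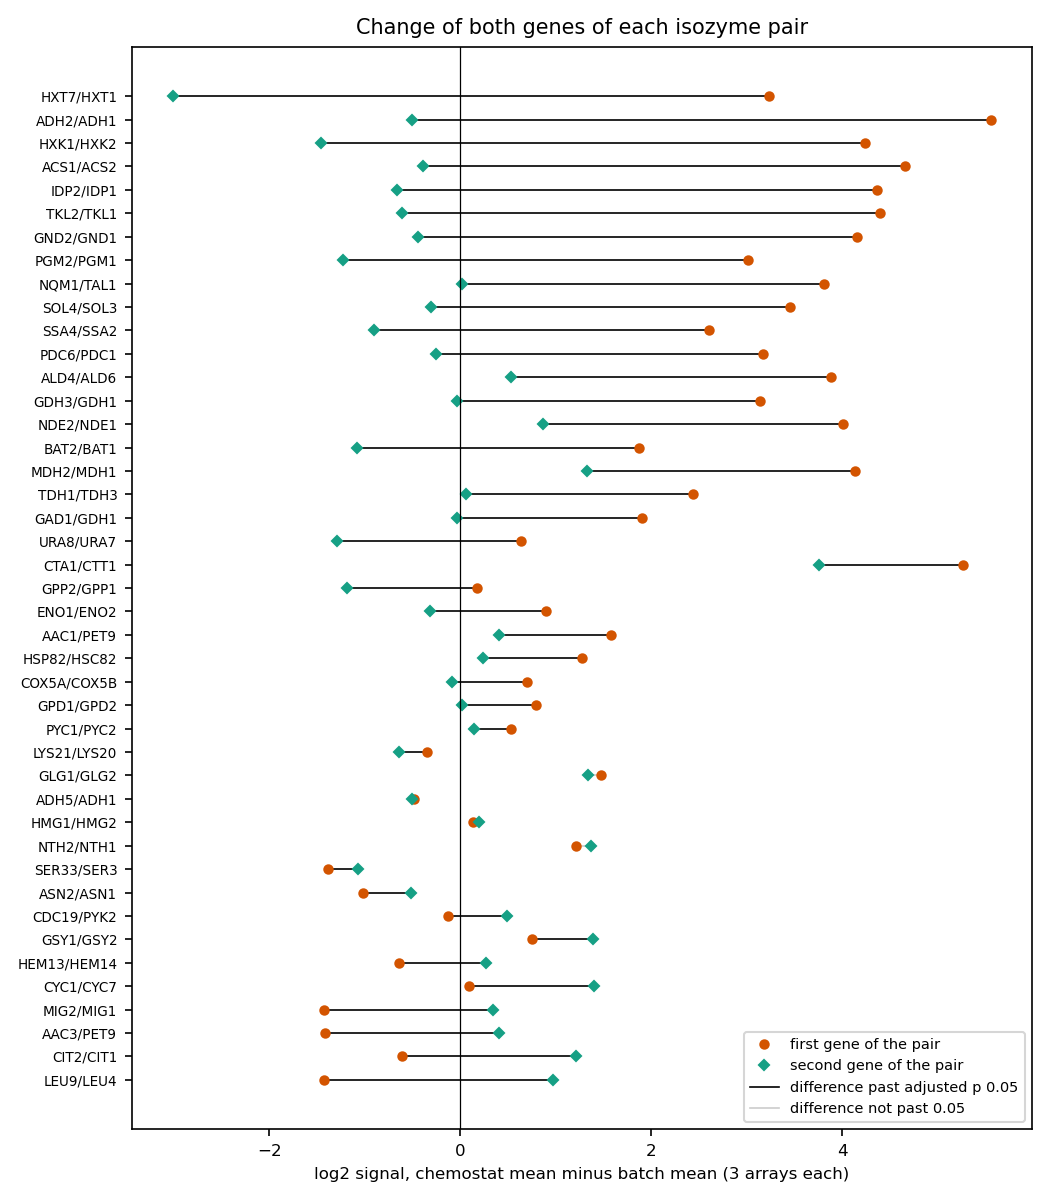
Change of each gene of 43 fixed gene pairs (log2 signal, chemostat minus batch, means of 3 arrays each), with circles for the first gene named and diamonds for the second, joined by a black line where the difference passed adjusted p 0.05 and a grey one where it did not. Genes at background in 1 group (HXT1, NDE2, AAC3 and CTA1) are drawn at their fitted change, and so is GDH3, whose batch mean lies below the percentile of the batch arrays themselves. The pair ADH2/ADH1 spans from 5.56 to -0.50, and the pair HXK1/HXK2 from 4.25 to -1.46.

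No chromosome stood apart. None of 16 chromosomes passed camera (smallest adjusted p = 0.968; 0 at an unadjusted p under 0.05), and their medians ran from -0.14 to 0.04. The 302 genes within 30 kb of a chromosome end had a median of 0.05 against -0.07 for all others, with 128 higher and 85 lower (camera p = 0.013; p = 0.061 with an estimated correlation).

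Probe sets for S. pombe, a yeast that was not part of the samples, gave a faint and nearly one-sided shift. In a limma fit of these 1746 probe sets alone, 364 passed, 11 higher and 353 lower in chemostat. None of these changes reached 1.5-fold (602 probe sets had an unadjusted p under 0.05), and they ran from -0.30 to 0.09 with a median of -0.03. The largest were those of rpl13, which fell by 0.30 (SE 0.042), did4, which fell by 0.25 (SE 0.023), and gua1, which fell by 0.24 (SE 0.024). The count was 216 without chemostat replicate 8, 225 without chemostat replicate 9, 151 with arrays centred on the S. pombe median, 21 with background subtracted and 599 with array weights.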

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

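The S. pombe and unannotated probe sets lie outside the gene comparison, and both drew attention because they differed between groups with no target named for them in these samples. Of the S. pombe probe sets, 364 of 1746 passed limma's adjusted threshold, 353 of them lower in chemostat. All changes lay between -0.30 and 0.09, and none reached 1.5-fold. The 10 ways to part 6 arrays into 3 and 3 are too few for a share under 0.05: the real grouping gave 364 (1 of 10 splits gave as many) and the highest other split, which mixes both modes, gave 0.

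Among 3470 unannotated probe sets, 342 lay above background and 712 passed limma's threshold. Of those 712, 36 changed 2-fold or more, 27 higher and 9 lower in chemostat. The median signal of the unannotated class was 5.17, against 5.16 for the S. pombe class. Many of its members may therefore be S. pombe probe sets without a lower-case symbol. The largest of the 27 rises among probe sets above background in both groups was 3.27 (SE 0.039), from 8.04 in batch to 11.31 in chemostat. The largest fall was -1.84 (SE 0.11). Neither their targets nor a cause was tested.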

How the results depend on the processing

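Background subtraction and the comparison of batch 2 and 3 with chemostat 8 and 9 were chosen after the data were seen; all other alternatives were planned. Where a result changed, the cause was not tested unless given. Over the alternatives run, named genes and pairs gave 3016 values, of which 2973 kept direction and side of the threshold, 29 lost a call, 11 gained one and 3 turned direction; lists gave 559, of which 518 kept both. No paired analysis was possible because the groups share no replicate number. The pseudocounts of 1 and 64 were not run, because the values are already logarithms. Low signal limits changes near the floor, and 285 genes lay below background in both groups.

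The gene counts lay from 3940 to 4246 (4271 with all arrays) when 1 array was left out, from 1660 to 1808 higher and from 2280 to 2438 lower. Quantile normalization gave 1637 higher and 2730 lower, against 1829 and 2442 for the values as deposited. Centring on the S. pombe median gave 1948 and 2329, and centring on the gene median gave 1817 and 2465. The balance of rises and falls thus moved with the scaling between arrays. Limma's treat left 1165 genes, 601 higher and 564 lower, by its construction, since it asks for 1.5-fold. The S. pombe count of 364 became 151 with arrays centred on the S. pombe median, 599 with array weights, 21 with background subtracted and from 216 to 381 with 1 array left out.

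Quantile normalization ended the calls of the high-affinity hexose transporters (0.13), alpha-cell markers (0.25) and meiosis markers (0.034), and turned the camera direction of the hypoxic genes (-0.28). Removing dim genes ended the call of the high-affinity transporters (1.51) with fewer members tested. Leaving out 1 array gave medians from 0.078 to 0.10 for the proteasome, whose call ended without batch replicate 1 (0.085), from 0.38 to 0.445 for alpha-cell markers, whose call ended without chemostat replicate 4 (0.39), from -0.42 to -0.29 for the pheromone pathway, which passed without that array, and from -0.32 to -0.024 for iron and copper genes, whose camera direction turned without batch replicate 2. The ADH5 and ADH1 difference, never past the threshold, ran from -0.029 to 0.090 and was -0.0059 without chemostat replicate 8. With 2 arrays per group it was -0.047, the proteasome (0.089) and alpha-cell markers (0.42) lost their calls, the pheromone pathway passed (-0.41), and the lowest correlation within a group became 0.997. Background subtraction moved the low-affinity transporters to -3.75.

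With an estimated correlation the medians stay as they were by construction and every list call ended: high-affinity transporters (0.40), gluconeogenesis (2.92), tricarboxylic acid cycle (1.19), respiratory chain (0.70), peroxisome (0.71), trehalose and glycogen (1.47), stress (3.001), cytosolic ribosomal proteins (-0.59), ribosome biogenesis (-0.82), RNA polymerases (-0.92), mitochondrial ribosomal proteins (-0.31), synthetases (-0.72), amino acids (-0.51), nitrogen (0.37), purines and pyrimidines (-0.92), thiamine (0.45), proteasome (0.10), autophagy (0.65), sugar use (0.34), alpha-cell markers (0.41) and meiosis (0.21). The few residual degrees of freedom limited the power of that setting, and most of its correlations lay above the preset. These ended calls can therefore be taken as neither overturned nor upheld. With fry, which does not compare a list with other genes, ethanol and acetate (0.14), ergosterol (-0.38), pentose phosphate (0.022), a-cell markers (-1.14) and the pheromone pathway (-0.35) passed, and glycolysis (0.022) and phosphate (0.0088) turned to lower without passing.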

Other observations

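The families below were grouped by the letters of their symbols after the data were seen, and the tests of batch replicate 1, mating markers and large rises were also chosen after those results were seen. Of 197 families tested with camera, 34 passed, 20 lower and 14 higher in chemostat, and none passed with an estimated correlation (smallest adjusted p = 0.672). Genes for the vacuolar proton pump and its assembly (VMA) fell in 14 of 15 cases with a median of -0.64 (camera adjusted p = 0.00222). Genes for tRNA modification (TRM) fell in 14 of 15 cases (median -0.66, camera adjusted p = 0.00381), and so did 9 of 9 genes named TIF (median -0.60) and 7 of 7 named GCD (median -0.62). Most of these encode translation initiation factors, but TIF6 acts in ribosome biogenesis, and GCD10 and GCD14 encode a tRNA methyltransferase. Protein glycosylation genes (ALG) fell in 11 of 12 cases and genes for glycosylphosphatidylinositol anchors (GPI) in 12 of 13. Genes named RPB fell in 8 of 9 cases (median -0.75, camera adjusted p = 0.030). RPB8, which is also in the list of RNA polymerase I and III subunits, is one of the genes named RPB. In the other direction, 12 of 14 FMP genes, named for proteins found in mitochondria, rose (median 1.30), as did 6 of 6 MIC genes of the inner membrane organizing complex (median 0.43).

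The splits of 6 arrays into 3 and 3 number 10, too few for a share under 0.05, and each other split mixes both modes within its groups, which keeps its counts of genes and pairs low. The real grouping gave 4271 genes and 39 isozyme pairs with adjusted p under 0.05, and the highest other split gave 0 of each (1 of 10 splits as large for both). For gene lists with the preset correlation the real grouping gave 21 and the highest other split 24, and 6 of 10 splits gave as many. Part of the mode difference stays in each other split, and camera compares a list with other genes. The list count of the splits therefore cannot decide whether the list calls exceed chance.

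Batch replicate 1 stood apart from the other batch samples: of 59 genes more than 0.5 higher in it, 40 were higher and 8 lower in chemostat. A single share of chemostat RNA mixed into that sample would lift all genes far higher in chemostat. The share implied by all 204 rises of 4-fold or more (median 1.25%) gives 12.7% of the excess of the 59 genes (median over genes), and at least 50% for 5 of them, which counts against this mixing for the 59 as a whole. The 59 were chosen by that excess, and 13 of them had a fitted fall, which mixing could not lift. Both lower the percentage. A shift common to all genes in the deposited values of that array is argued against by a median difference of -0.016 over all genes. The gene medians of all arrays were nearly equal as deposited. The median therefore cannot show whether a scaling fault that depends on signal level remained. A difference in growth stage at sampling may remain; no biological explanation was tested.

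Of 7 a-cell markers 4 fell and 2 rose, and of 4 alpha-cell markers 3 rose, a list call that ended with an estimated correlation, after quantile normalization and without chemostat replicate 4. Alpha cells in place of a cells would lower all a-cell markers, but 3 of 7 did not pass as lower. A small share of alpha cells, for the rises, cannot be told apart from a change within a cells, since 1 of 4 alpha-cell markers did not pass as higher and the others were dim. The cultivation mode itself stays open and untested.

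Changes of 4-fold or more were mostly rises (204 rises, 16 falls). Between-array scaling of the kind that quantile normalization removes is argued against, since rises made up 92.5% of such changes after it (196 rises, 16 falls). Dim probe sets, whose falls the floor could hide, are argued against as the whole cause by a share of 92.7% (191 rises, 15 falls) among 4508 genes whose mean over all arrays was at least 1 above background, where rises and falls have equal room. As a hypothesis found on these same data, the excess may belong to the cultivation mode; other steps of the authors' normalization were not tested.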
